A study of Mus musculus with 3 samples.

How the data were processed

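RNA was extracted by the submitters from intestinal epithelial cells that had been detached from the gut of C57BL/6 mice with EDTA in a buffered salt solution, and total RNA was made into Illumina libraries, per the labels' protocols. The stretch of gut, the age and sex of the mice, and the dose and time of infection are not given in the sources used here. The deposited table held 54672 genes with FPKM values (reads scaled by gene length and by library size), as named in the deposited file, for 3 libraries, 1 each of wild-type, germ-free and S. Typhimurium-infected mice. Bowtie 0.12.2 and the mm9 build are named in the submitters' processing notes, without a role, and the counting tool, annotation release and use of strand are not given in the sources used here. The table also gave Ensembl identifiers, symbols, coordinates, gene lengths and biotypes. Of 20874 protein-coding genes with a RefSeq symbol, 83.4% start within 1 kb of their place in GRCm38.p6, so the coordinates printed are those of the deposited table and not mm9. The 140 entries without a symbol were left out of the gene names.

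The deposited FPKM times gene length was a whole multiple of 1 step in each library for 100% of the values above 0, within a tolerance of 0.001, so the whole reads behind each value were recovered. They summed to 18211323 (wild-type), 18235453 (germ-free) and 20866552 (infected). The steps matched effective library sizes that equal median-of-ratios size factors of 1.043, 0.791 and 1.219 times the geometric mean of the totals. The authors' scaling was therefore computed over these 3 libraries, and the germ-free values are divided by a smaller size than their total. Sums of FPKM were 347703, 547890 and 327592.

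All steps from there were computed here with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Where entries shared a symbol the one of highest mean was kept. A gene was compared if it had at least 1 FPKM in 1 or more libraries, which gave 12310 genes, 10649 protein-coding and 453 long non-coding. With 1 library per group no test between conditions was possible and no p-value was computed. A gene was called higher or lower when log2((FPKM + 1)/(wild-type FPKM + 1)) was at least 1 or at most -1, which understates differences of low genes. Ratios printed for single genes are ratios of FPKM with exact (Clopper-Pearson) 95% intervals from the recovered reads, and compare those libraries, not the conditions. A gene with 0 reads in 1 library was given a floor of 3 reads in that library and its ratio written as "at least". Reads are not independent molecules, so intervals and floors cover counting error only.

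The 39 gene lists, the size rule, the rule for named genes and 13 alternatives were fixed before the data were examined. Each list with at least 4 expressed members was described by its median log2 ratio and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to lie below or above the random lists when its percentile was under 2.5 or over 97.5, and the percentile describes these libraries only. The genes named were the 12 of largest absolute log2 ratio per direction with at least 5 FPKM in the higher library and a symbol that is not a clone name, at most 2 per symbol stem. To these were added the 5 largest differences per direction among long non-coding genes, up to 3 members per direction and the most abundant member of each list, and the sex-linked transcripts. Ciita and the homeobox and interferon genes of the last part were named after their values were seen. Some genes that the rule names are not reported here. For the overlap of the 2 comparisons, 200 sets of 3 unchanged libraries sharing a control were simulated. The alternatives were other pseudocounts, filters, scalings, size rules, gene classes and list summaries, and 4 more were added after seeing the data.

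The procedure was tested on simulated data in which 200 of 12310 genes were changed. Only counting noise was simulated, without spread between mice, so the counts of unchanged genes are not rates of false calls. For the germ-free comparison 80% of genes changed 3-fold and 94% of those changed 8-fold passed the rule, and 45 of 12110 unchanged genes did. For the infected comparison the shares were 84% and 99%, with 37 unchanged genes past the rule. Among random lists without a change 3% lay outside in either comparison, and 100% of lists given a shift did. Those lists were drawn gene by gene, so the 3% does not cover lists of genes that vary together.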

Results

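Messenger RNA and long non-coding RNA were measured by sequencing in intestinal epithelial cells, the absorptive and secretory cells that line the gut, of C57BL/6 mice. The 3 groups were uninfected wild-type mice, germ-free mice, which are raised without microbes, and wild-type mice infected with Salmonella enterica serovar Typhimurium (S. Typhimurium), a bacterium that invades the gut epithelium. Each group was 1 library and there were no replicates, so no difference given here could be set against a spread between mice, and the intervals beside ratios are 95% intervals that cover counting error only. The wild-type, germ-free and infected libraries held 18211323, 18235453 and 20866552 reads assigned to genes, and 20948, 18780 and 20806 genes had at least 1 read.

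The libraries also differed in composition and in sex-linked transcripts. Mitochondrial genes took 19.6% of the reads of the germ-free library, 9.06% of the wild-type library and 6.99% of the infected library. Xist, the RNA that silences an X chromosome in female cells, was at 9.68 FPKM in the germ-free library and listed at 0 in the wild-type library. The Y-linked Eif2s3y was at 8.13 FPKM in the wild-type library, 9.85 FPKM in the infected library and 0 in the germ-free library, and Ddx3y and Kdm5d had the same order of presence and absence. The germ-free library therefore differed from the other 2 in sex-linked transcripts as well as in colonisation, and every germ-free value below carries both differences.

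The comparison of germ-free with wild-type cells addressed how epithelial transcripts differ when microbes are absent. Antigen presentation and interferon genes were lower in the germ-free library, by more than 100-fold for Cd74, H2-Aa and Ifit1. All 24 expressed members of the type I and III interferon list and all 7 of the MHC class II list were past the 2-fold rule. The medians of mitochondrial-encoded transcripts, cholesterol synthesis genes and drug-metabolising enzymes lay above matched random lists, with 9 of 15, 8 of 21 and 6 of 22 members past the rule as higher. In all, 525 genes were at least 2-fold higher and 566 at least 2-fold lower among 12310 genes compared. Of these 1091 genes, 1075 had a counting interval that excluded a ratio of 1 or had 0 reads in 1 of the libraries compared. Genes of the latter kind were counted without an interval, however few their reads.

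MHC class II genes, which present peptides to helper T cells, had a median log2 ratio of -4.51, below the matched random lists. Cd74, the invariant chain of class II molecules (chromosome 18, 60803848 to 60812646), was at 351 FPKM in the wild-type and 2.68 FPKM in the germ-free library, 131-fold lower (101 to 173). H2-Aa, a class II alpha chain (chromosome 17, 34282744 to 34287827), was 111-fold lower (72.4 to 179), and H2-Ab1, a class II beta chain, was 49.1-fold lower (37.1 to 66.3). Ciita, the master activator of class II transcription, was at 1.32 FPKM in the wild-type and 0.0209 FPKM in the germ-free library. In the MHC class I and immunoproteasome list 12 of 14 members were lower and none higher, with a median of -1.64. Psmb8, an immunoproteasome subunit, was 23.5-fold lower (18.3 to 30.6), and Tap1, a peptide transporter, was 11.9-fold lower (10.4 to 13.6). B2m, the light chain of class I molecules and the most abundant member, was at 1566 FPKM in the wild-type and 253 FPKM in the germ-free library. H2 genes resemble one another, so reads may be split among them and single values are uncertain.

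The type I and III interferon list, genes induced by antiviral interferons, had a median log2 ratio of -3.48. Ifi27l2a was 238-fold lower (102 to 736), and Isg15, a ubiquitin-like modifier (chromosome 4, 156199424 to 156200818), was 89.6-fold lower (60.1 to 140). Ifit1, which binds foreign RNA, was at 55.0 FPKM in the wild-type and 0.150 FPKM in the germ-free library, 367-fold lower (169 to 1002). Oasl2, a member of the oligoadenylate synthetase family, was 118-fold lower (88.6 to 161), and Rtp4 was 84.9-fold lower (50.5 to 156). Of the 22 expressed interferon-gamma targets, 16 were lower and none higher, with a median of -1.71 that moved to -1.91 with the gene at 0 reads set at its bound. Zbp1, a sensor of nucleic acids in the Z form, was 71.8-fold lower (47.7 to 114), and Iigp1, an immunity-related GTPase, was 225-fold lower (87.6 to 826). Ifit1bl1, Slfn4 and Ly6a, also among the 12 genes furthest below wild-type, were 96.2-fold (76.1 to 124), 53.9-fold (45.3 to 64.7) and 25.5-fold (22.5 to 29.0) lower. Markers of T cells and intraepithelial lymphocytes, which can release interferon-gamma, were lower in the same library (median -1.08, 7 of 14 members). The granzymes Gzma and Gzmb were 49.1-fold (20.8 to 152) and 135-fold (23.9 to 5361) lower.

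Antimicrobial and defence genes had a median log2 ratio of -0.76, with 10 of 23 members lower and 2 higher. Ang4, an angiogenin of secretory cells (chromosome 14, 51763878 to 51773590), was at 295 FPKM in the wild-type and 4.49 FPKM in the germ-free library, 65.6-fold lower (49.4 to 89.2). Reg3b, a lectin that binds bacteria, was 8.64-fold lower (7.35 to 10.2), and Duox2, an oxidase that makes hydrogen peroxide at the epithelial surface, was 13.5-fold lower (11.03 to 16.61). The 2 members past the rule in the other direction were Saa3, a serum amyloid, 4.51-fold higher (3.38 to 6.09), and Sprr2a1, a small proline-rich protein, 2.15-fold higher (2.09 to 2.21). Inflammasome and pattern recognition genes lay below the random lists at -0.19 with 3 of 27 lower, among them Casp4, 3.07-fold lower (2.58 to 3.66), and Gsdmd, the pore-forming gasdermin, 2.51-fold lower (2.33 to 2.70). The NF-kB list lay below at -0.55 with 2 of 15 lower, Tnf and Ccl7. Without the filter on low values its median was -0.17 and inside the random lists.

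Medians of 4 lists of secretory and chemosensory cell markers also lay below the random lists. Goblet cell markers had a median of -0.73, with 5 of 15 members lower and 1 higher. Muc2, the main gel-forming mucin of the gut, was 4.08-fold lower (4.01 to 4.15) and Clca1, a secreted mucus-processing protease, was 5.90-fold lower (5.75 to 6.05). Tff3, a trefoil peptide of the same cells, was 2.06-fold higher (2.00 to 2.11). Tuft cell markers had a median of -1.09 with 5 of 8 lower, among them Trpm5, a cation channel of chemosensory cells, 7.61-fold lower (5.04 to 11.99). Enteroendocrine markers had a median of -0.72 with 2 of 11 lower and 1 higher. The gut hormone Pyy was 4.32-fold lower (3.34 to 5.66) and Chgb, a granule protein, 3.92-fold lower (3.38 to 4.56), while secretin (Sct) was 2.21-fold higher (1.89 to 2.59). Paneth cell markers had a median of -0.84 with 4 of 10 lower, and Ang4 and Itln1 belong to both that list and the antimicrobial list. Stem cell markers lay below the random lists at -0.33 with 1 of 13 lower, Slc12a2. By the mean of the members (-0.30) they lay inside. Proliferation genes lay inside the random lists at 0.01, a value below 0 under each of the 5 other scalings, and Mki67, the marker of dividing cells, was the single member past the rule, 2.29-fold lower (2.08 to 2.53).

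Lists of energy, sterol and drug metabolism genes lay above the random lists. Of 15 mitochondrial-encoded transcripts 9 were higher and none lower, with a median of 1.43. The most abundant, mt-Co1, a subunit of cytochrome c oxidase, took 14.8% of the germ-free reads and 6.00% of the wild-type reads, and mt-Co2 was 10.7-fold higher (10.1 to 11.4). The short tRNA genes mt-Tq, mt-Ts2 and mt-Th and mt-Atp8 were also among the 12 genes furthest above wild-type, and reads of mitochondrial genes may be shared with nuclear copies, so single values are uncertain. Nuclear-encoded oxidative phosphorylation genes had a median of 0.95, above the random lists, with 12 of 30 higher and none lower as deposited and 0 of 30 past the rule as TPM. Uqcrq and Cox7a2, subunits of complexes III and IV of the respiratory chain, were 2.39-fold (2.30 to 2.48) and 2.27-fold (2.17 to 2.38) higher. Cholesterol biosynthesis genes had a median of 0.82 with 8 of 21 higher and none lower. Cyp51, a sterol demethylase, was 3.13-fold higher (2.95 to 3.32), and Tm7sf2, a sterol reductase, was 3.47-fold higher (3.03 to 3.98). Xenobiotic metabolism genes had a median of 0.87 with 6 of 22 higher and 1 lower. As TPM the medians of the mitochondrial-encoded, oxidative phosphorylation, cholesterol and xenobiotic lists were 0.78, 0.29, 0.19 and 0.24, and that of the mitochondrial-encoded list was 0.37 with quantile normalization, all above the random lists. Rescaling to TPM shifts the random lists as well, so a list's place among them could hardly change with it. Cyp2d26, a cytochrome P450 (chromosome 15, 82790101 to 82794294), was 7.07-fold higher (6.56 to 7.64), Aldh1a1, a retinaldehyde dehydrogenase, 4.26-fold higher (4.13 to 4.39), and Cyp3a25, read 0 times in the germ-free library, at least 13.1-fold lower.

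Other genes furthest above wild-type were Ctsf, a lysosomal protease, 10.3-fold (8.73 to 12.2), and Slc37a2, a sugar-phosphate exchanger, 8.58-fold (8.23 to 8.96). Ak4, an adenylate kinase of mitochondria, was 14.0-fold higher (11.3 to 17.5), St3gal5, a sialyltransferase, 6.36-fold (5.68 to 7.13), and Bnip3, a mitophagy receptor, 7.58-fold (6.14 to 9.44). Circadian clock genes lay above the random lists at 0.38 with 3 of 16 higher and 1 lower. Dbp was 3.30-fold higher (2.87 to 3.80) and Npas2 3.84-fold lower (3.08 to 4.83). The list moved inside the random lists without the filter on low values (0.050), among genes with at least 5 FPKM (0.285), with quantile normalization (0.209) and by the mean (0.149). The median was -0.25 after rescaling to TPM, and the hour of collection is not given in the labels.

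Absorptive genes differed gene by gene. Enterocyte brush border genes lay below the random lists at -0.44 with 4 of 16 lower, and Anpep, an aminopeptidase, was 7.55-fold lower (6.85 to 8.35). Among genes with at least 5 FPKM that median was 0.065. Lists of nutrient transporters (-0.15), proximal small intestine (-0.22), ileum (-0.046) and bile acid handling (-0.023) lay inside the random lists. So did colon markers (0.18), lipid absorption (0.087) and fatty acid oxidation (0.24), each of these with a median below 0 under 3 of the 5 other scalings. Within them Car1, a carbonic anhydrase of colonocytes, was 3.73-fold higher (3.70 to 3.75), Rbp2, a retinol carrier, 4.58-fold higher (4.03 to 5.22), and Fabp2, a fatty acid carrier, 2.44-fold higher (2.38 to 2.51). Apoa1, an apolipoprotein, was 9.06-fold lower (8.08 to 10.2) and Slc6a19, a neutral amino acid transporter, 7.38-fold lower (5.77 to 9.56). Tight junction genes lay below at -0.21 with 2 of 18 lower, of which Cldn2, a pore-forming claudin, was 3.04-fold lower (2.84 to 3.26). The stress lists gave -0.12 for the unfolded protein response, below the random lists with no member past the rule but inside them by the mean (-0.142), and 0.30 for immediate-early genes, inside them. Ribosomal protein genes (0.57), histones (0.27) and erythroid markers (-0.084) lay inside. Histones moved above the random lists among genes with at least 5 FPKM (1.379) and by the mean (0.417), and so did lipid absorption at 5 FPKM (0.616). The ribosomal, histone and immediate-early medians were below 0 after rescaling to TPM, the last under 4 scalings. Neutrophil and macrophage markers stood at -0.44 with 1 of 10 lower, at percentile 2.23, and moved inside (2.94) when random lists were matched on gene length.

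Long non-coding genes past the rule numbered 31 higher and 40 lower of 453. Besides Xist, 9130204K15Rik (chromosome 11, 79781979 to 79872394) was 12.1-fold higher (10.1 to 14.7), 9130221F21Rik 6.93-fold higher (4.90 to 10.03), and 1700003I22Rik, with 0 wild-type reads, at least 16.7-fold higher. Gm31105, 11.5-fold higher (4.13 to 44.7), lies antisense within the Gab1 locus, so without stated strand use its reads cannot be separated from those of Gab1. Gm3054 (chromosome 5, 137154029 to 137166070) was at 490 FPKM in the wild-type and 15.8 FPKM in the germ-free library, 31.1-fold lower (24.2 to 40.6). Gm33424 was 7.08-fold lower (4.64 to 11.3), Gm26532 3.64-fold lower (2.96 to 4.51), Gm17024, within Ifrd1, 12.5-fold lower (7.31 to 23.2), and the Y-linked Gm28588 at least 12.6-fold lower. In the list of well-characterised long non-coding RNAs 2 of 19 were lower, with a median of -0.39 below the random lists. Both are nuclear RNAs: Malat1 was 2.43-fold lower (2.32 to 2.54) and Neat1 2.39-fold lower (2.24 to 2.56).

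The balance of higher and lower genes in the germ-free library depended on scaling. As deposited 48.1% of the genes past the rule were higher, against 37.8% with size factors from genes at 1 FPKM or more in all 3 libraries, 33.3% with ratios centred by abundance and gene length, 20.9% after leaving out the 100 most abundant genes, and 7.2% as TPM. The median log2 ratio of all genes was 0.056 as deposited, -0.20 without the 100 most abundant genes and -0.52 as TPM, and the lists are read against random lists that carry the same shift. Ratios were also lower in longer genes, with a median of 0.27 among the shortest 2462 genes and -0.19 among the longest 2462. Abundant genes had higher ratios, with a germ-free median of 0.077 at a mean of at least 1 FPKM and 0.545 at 100 FPKM or more. In the infected library these medians were 0.027 and -0.05. Random lists were matched on mean expression, but germ-free ratios of single genes and counts of members past the rule carry this trend.

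**Figure D1:**
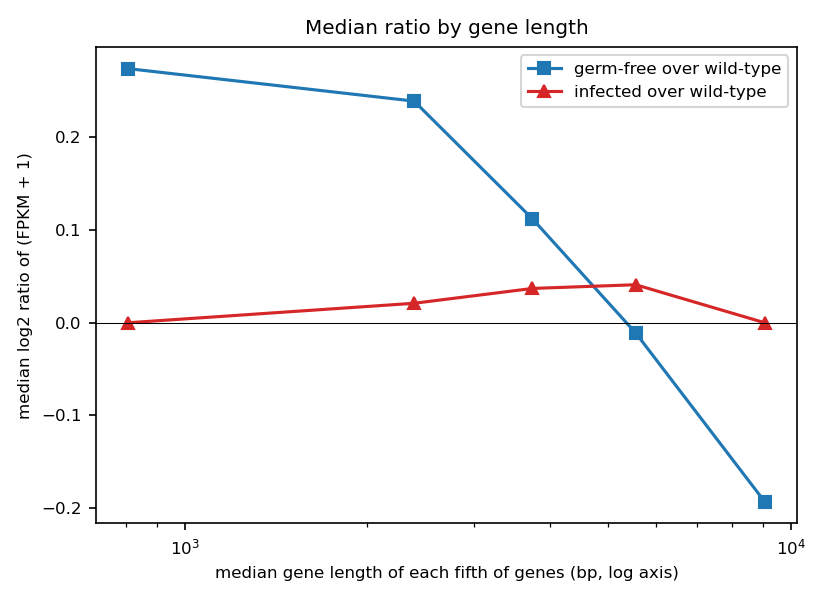
Median log2 ratio of FPKM + 1 (vertical axis) for 5 groups of 2462 genes by gene length in bp (horizontal log axis), for the germ-free library over wild-type (squares) and the infected library over wild-type (triangles). The germ-free medians run from 0.27 in the shortest group to -0.19 in the longest, and the infected medians stay between 0.00 and 0.041.

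The comparison of infected with uninfected wild-type cells addressed the epithelial transcript response to S. Typhimurium. In the infected library 14 of 23 defence genes, 8 of 15 NF-kB targets and chemokines, 11 of 22 interferon-gamma targets and 22 of 24 proliferation genes were past the rule as higher, among them Reg3b and Reg3g at 73.4-fold and 51.0-fold. As lower were 8 of 10 Paneth cell markers, 10 of 16 enterocyte, 9 of 19 lipid absorption and 14 of 22 drug metabolism genes, with Apoa1 62.8-fold below wild-type. In all, 665 genes were at least 2-fold higher and 559 at least 2-fold lower. Of these 1224 genes, 1199 had a counting interval that excluded a ratio of 1 or had 0 reads in 1 of the libraries compared.

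Of 23 antimicrobial and defence genes 14 were higher and 2 lower, with a median log2 ratio of 1.55, above the random lists. Reg3b (chromosome 6, 78370657 to 78373466) was at 81.2 FPKM in the wild-type and 5963 FPKM in the infected library, 73.4-fold higher (70.1 to 76.9). Its neighbour Reg3g, a lectin that kills Gram-positive bacteria, was 51.0-fold higher (47.0 to 55.6). The 2 genes are alike in sequence and may share reads. Duoxa2, the maturation factor of Duox2, was 12.03-fold higher (10.6 to 13.8). The 2 lower members were Itln1, a lectin, 8.29-fold (6.38 to 10.9), and Ang4, 5.16-fold (4.81 to 5.55). In the NF-kB and chemokine list 8 of 15 were higher and none lower, with a median of 1.52. Cxcl5 and Cxcl2, chemokines that attract neutrophils, were 116-fold (44.9 to 426) and 31.0-fold (13.0 to 96.6) higher, and the cytokine Il1b was 18.6-fold higher (11.6 to 31.7). Neutrophil and macrophage markers were higher in the same library, with 5 of 10 members past the rule and a median of 0.99. The macrophage complement genes C1qa and C1qb were the 2 below wild-type, C1qa at a ratio of 0.438 (0.296 to 0.64) and C1qb at 1.39 and 0.672 FPKM in the wild-type and infected libraries. S100a9 and S100a8, calprotectin subunits, were 25.5-fold (9.69 to 94.99) and 19.1-fold (8.56 to 53.0) higher, at 9.81 and 8.31 FPKM, and both are also members of the defence list. Reads from epithelial cells and from leukocytes in the preparation cannot be told apart in these values.

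Interferon-gamma targets had a median of 1.09 with 11 of 22 higher and none lower. Ido1, a tryptophan-degrading enzyme (chromosome 8, 24584136 to 24597009), was at 1.98 FPKM in the wild-type and 62.0 FPKM in the infected library, 31.3-fold higher (24.7 to 40.1). The GTPases Tgtp1 and Iigp1 were 8.36-fold (6.98 to 10.1) and 4.97-fold (4.67 to 5.29) higher. Type I and III interferon genes went the other way, with 12 of 24 lower, none higher and a median of -0.96. Ifit3 was 5.47-fold lower (4.52 to 6.65), Ifit1 4.12-fold lower (3.81 to 4.46) and Ifi27l2a 3.90-fold lower (3.52 to 4.33). MHC class II (0.18) and class I (0.20) lists lay inside the random lists, and H2-T23, a non-classical class I gene, was the single member past the rule, 2.21-fold lower (2.15 to 2.27). Inflammasome genes lay inside at 0.005, a value that changed sign under 3 scalings, with 2 of 27 higher and 1 lower. The higher members were Ripk3, a kinase of necroptosis, 3.60-fold (3.28 to 3.96), and Ripk2, the kinase downstream of Nod receptors, 3.32-fold (2.84 to 3.91).

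Proliferation genes were higher in 22 of 24 cases, with a median of 1.82. Ube2c, which targets mitotic cyclins for degradation, was 5.15-fold higher (4.66 to 5.70), Ccna2, cyclin A, 5.01-fold (4.58 to 5.503), and Top2a, a DNA topoisomerase of dividing cells, 4.93-fold (4.64 to 5.25). Histones had a median of 0.57 with 3 of 10 higher, and among genes with at least 5 FPKM the median was -0.049. Stem cell markers lay inside the random lists at -0.12. Olfm4 was 26.5-fold lower (8.69 to 132) from 1.15 FPKM. Paneth cell markers had a median of -2.84 with 8 of 10 lower. The most abundant of them in the wild-type library, Ang4 (295 FPKM), is also in the colon and defence lists, so the list need not track Paneth cells. The defensins Defa24 and Defa22 were 60.4-fold (29.0 to 151) and at least 70.5-fold lower, the latter read 0 times in the infected library, and the lysozyme Lyz1 was 27.0-fold lower (15.9 to 50.01). Defensin genes are near-identical, so single values are uncertain. Goblet cell markers stood at -0.58 with 2 of 15 lower, Clca1 at 3.29-fold (3.23 to 3.34) and Klk1, a kallikrein, at 2.37-fold (2.32 to 2.43). Enteroendocrine markers lay inside at -0.13. Tac1, the precursor of substance P, was 20.7-fold higher (16.4 to 26.3) and Sct 2.12-fold lower (1.72 to 2.61). Tuft cell markers were at percentile 2.28 with a median of -0.44 and no member past the rule, and moved inside under 6 alternatives, among them matching on gene length (percentile 4.22).

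Lists of differentiated enterocyte functions lay below the random lists. Brush border genes had a median of -1.23 with 10 of 16 lower, and Anpep was 10.99-fold lower (9.99 to 12.1). Lipid absorption genes had a median of -0.90 with 9 of 19 lower. Apoa1 (chromosome 9, 46228580 to 46230466) was at 153 FPKM in the wild-type and 2.44 FPKM in the infected library, 62.8-fold lower (49.6 to 80.8), and Fabp2 was 5.70-fold lower (5.42 to 5.99). Fatty acid oxidation and PPAR targets had a median of -1.17 with 14 of 23 lower and none higher. Pdk4, a kinase that inhibits pyruvate dehydrogenase, was 15.9-fold lower (13.5 to 18.8), and Angptl4, an inhibitor of lipoprotein lipase, 90.0-fold lower (41.0 to 246). Xenobiotic metabolism genes had a median of -1.10 with 14 of 22 lower. Cyp2c55 (chromosome 19, 39007019 to 39042693) was 40.9-fold lower (37.9 to 44.2), Cyp2c68 19.4-fold lower (14.8 to 26.0), and Abcb1a, a drug efflux pump, 9.55-fold lower (9.10 to 10.04). The carboxylesterases Ces1d and Ces1g were 15.1-fold (12.5 to 18.4) and 10.2-fold (8.96 to 11.6) lower.

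Region marker lists lay below the random lists: proximal small intestine at -2.31 (5 of 7 lower), ileum at -1.05 (5 of 10) and colon at -0.96 (10 of 22 lower and 1 higher). Rbp2 was 8.60-fold lower (6.20 to 12.2), the bile acid carrier Fabp6 4.27-fold lower (3.62 to 5.06), and the water channel Aqp8 5.65-fold lower (5.31 to 6.02), while Aqp4 was 2.23-fold higher (2.16 to 2.30). Without the filter on low values the proximal median was -0.005 and inside the random lists. Of 14 proximal markers 7 were expressed, and Gip was listed at 0 in all 3 libraries. The highest in the wild-type library was Rbp2 at 15.8 FPKM, against 5160 FPKM for Car1 of the colon list. A fall of the proximal list therefore need not be a loss of small-intestinal cells. Nutrient transporters (-0.17) and bile acid handling (-0.32) lay inside, and Slc6a19 was 20.7-fold lower (15.0 to 29.4). Tight junction genes lay inside at -0.22, and Cldn4 was 4.45-fold lower (3.95 to 5.01).

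Cholesterol biosynthesis genes had a median of 0.73 with 5 of 21 higher and none lower, the mevalonate pathway enzymes Mvd and Mvk being 2.62-fold (2.38 to 2.88) and 2.40-fold (2.17 to 2.67) higher. The unfolded protein response list had a median of 0.57 with 5 of 20 higher. Asns, asparagine synthetase, was 3.12-fold higher (2.83 to 3.45) and Hsp90b1, a chaperone of the endoplasmic reticulum, 2.46-fold higher (2.38 to 2.55). Immediate-early genes stood at percentile 2.46 with a median of -0.27 and moved inside the random lists under 5 alternatives, among them the mean of the members (-0.045), yet the 2 members past the rule, the heat shock genes Hspa1b and Hspa1a, were 2.90-fold (2.71 to 3.10) and 2.94-fold (2.66 to 3.25) higher. Circadian genes had a median of -0.69 with 1 of 16 lower. Mitochondrial-encoded transcripts had a median of -0.51 with 2 of 15 lower, while oxidative phosphorylation (0.065) and ribosomal protein genes (0.15) lay inside. T cell markers stood at -0.72 with 2 of 14 lower, the cytokine Ccl5 and Gzma. Erythroid markers stood at -0.94 with 1 of 4 lower, Hbb-bs. No B or plasma cell marker reached 1 FPKM in any library, and 2 stromal markers (Vim and Tagln) and 1 pancreatic marker (Cela1) did, too few to set against random lists. Sex-linked transcripts had a median of 0.003.

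Further genes furthest above wild-type included Lrg1, a secreted glycoprotein of the acute phase (chromosome 17, 56119678 to 56122001), at 0.0714 FPKM in the wild-type and 177 FPKM in the infected library, a ratio of 2473 (684 to 20425). Clca4b was 36.3-fold higher (33.7 to 39.2), Mfsd2a, a lysophospholipid transporter, 42.7-fold (29.2 to 65.1), Slpi, a protease inhibitor, 13.2-fold (10.8 to 16.2), and Ly6c1 13.2-fold (11.7 to 14.9). Gapdh, a glycolytic enzyme with many pseudogenes, was at 2.24 FPKM in the wild-type and 39.1 FPKM in the infected library, and its reads may be shared with those copies.

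Long non-coding genes past the rule numbered 13 higher and 28 lower of 453. AI506816 was 5.63-fold higher (5.26 to 6.03) and Gm45397 12.9-fold higher (6.62 to 28.9). Gm16015, Gm48809 and AC113595.1 overlap Cd38, Cog5 and Apobec3, and their ratios of 5.38 (3.04 to 10.2), 6.32 (4.61 to 8.87) and 8.64 (6.03 to 12.8) cannot be separated from those genes. Gm33424 was 8.72-fold lower (5.94 to 13.2), Gm11496 3.88-fold lower (2.52 to 6.15) and Gm4285 3.89-fold lower (2.66 to 5.82). Gm47118 and Gm15998, 5.99-fold (2.77 to 14.8) and 16.9-fold (7.89 to 43.0) lower, overlap Edn1 and Efna3. The well-characterised list lay inside the random lists at -0.096.

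**Figure D2:**
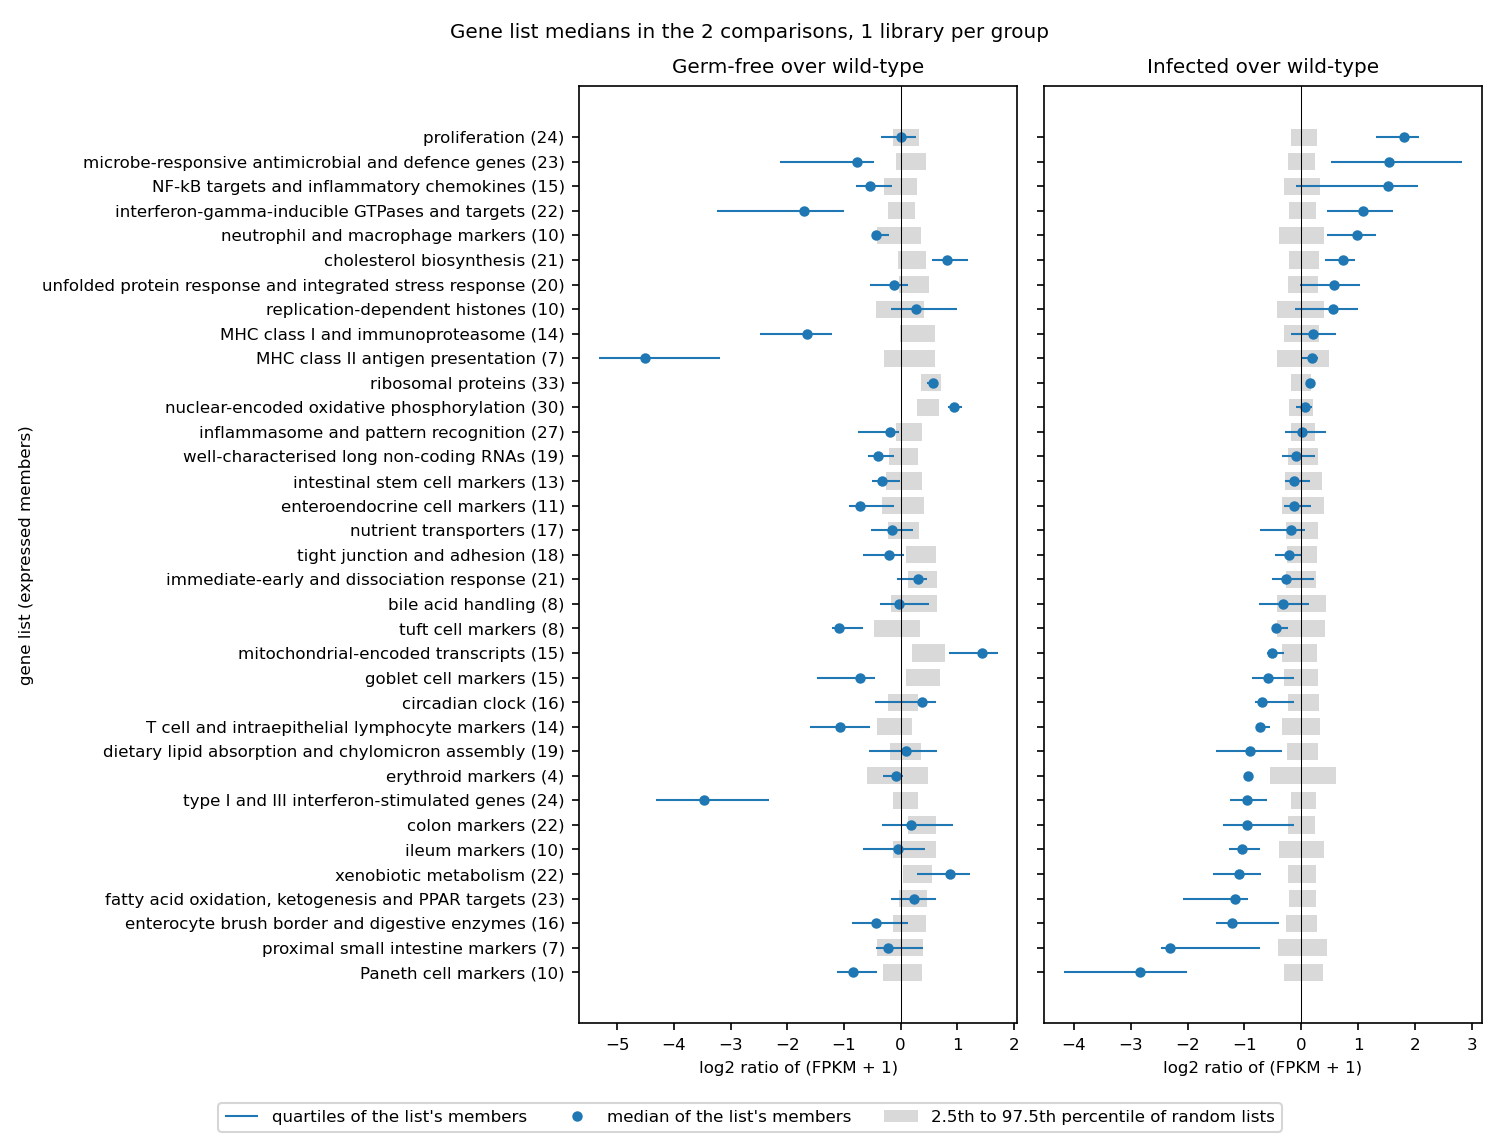
Median log2 ratio of FPKM + 1 over wild-type (horizontal axis) for the tested gene lists other than sex-linked transcripts, with the number of expressed members in brackets, in the germ-free (left) and infected (right) library. Points are medians, blue lines the quartiles of members and grey bars the central range of random lists; MHC class II stands at -4.51 on the left and proliferation at 1.82 on the right.

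Lists outside the random lists numbered 24 of 36 in the germ-free comparison, 5 above and 19 below. In the infected comparison they numbered 24, 8 above and 16 below. For lists of genes drawn at random 1.8 would be outside. Genes of a fixed list can vary together and some lists share members, so 1.8 gauges neither chance for such lists nor spread between mice. Both comparisons used the same wild-type library, and lists outside in the same direction in both may owe that shared direction to it. They include type I and III interferon genes, goblet, Paneth and T cell markers and cholesterol genes. In all, 30 genes were higher in both and 125 lower in both, against 28.4 and 25.7 for independent lists and 165 and 186 in simulated unchanged libraries that share the control. That simulation called 670 genes per direction, more than observed, so its noise is too large, and the effect of the shared library on the overlap could not be separated. The covariance of the log2 ratios across genes was 0.051, against 0.196 in the simulation, a difference of -0.145. Another 52 genes were higher in germ-free and lower in infected cells, and 48 the reverse, against 23.8 and 30.6 for independent lists. Set directly against the germ-free library, the infected library had 24 of 24 type I and III interferon genes higher, with a median of 2.29, and a cholesterol median of -0.10, inside the random lists. In that comparison Paneth markers lay below the random lists (-1.68), goblet markers above them (0.31) and T cell markers inside (0.42). The lower Paneth markers of the infected library and the lower interferon genes of the germ-free library thus did not need the wild-type library.

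**Figure D3:**
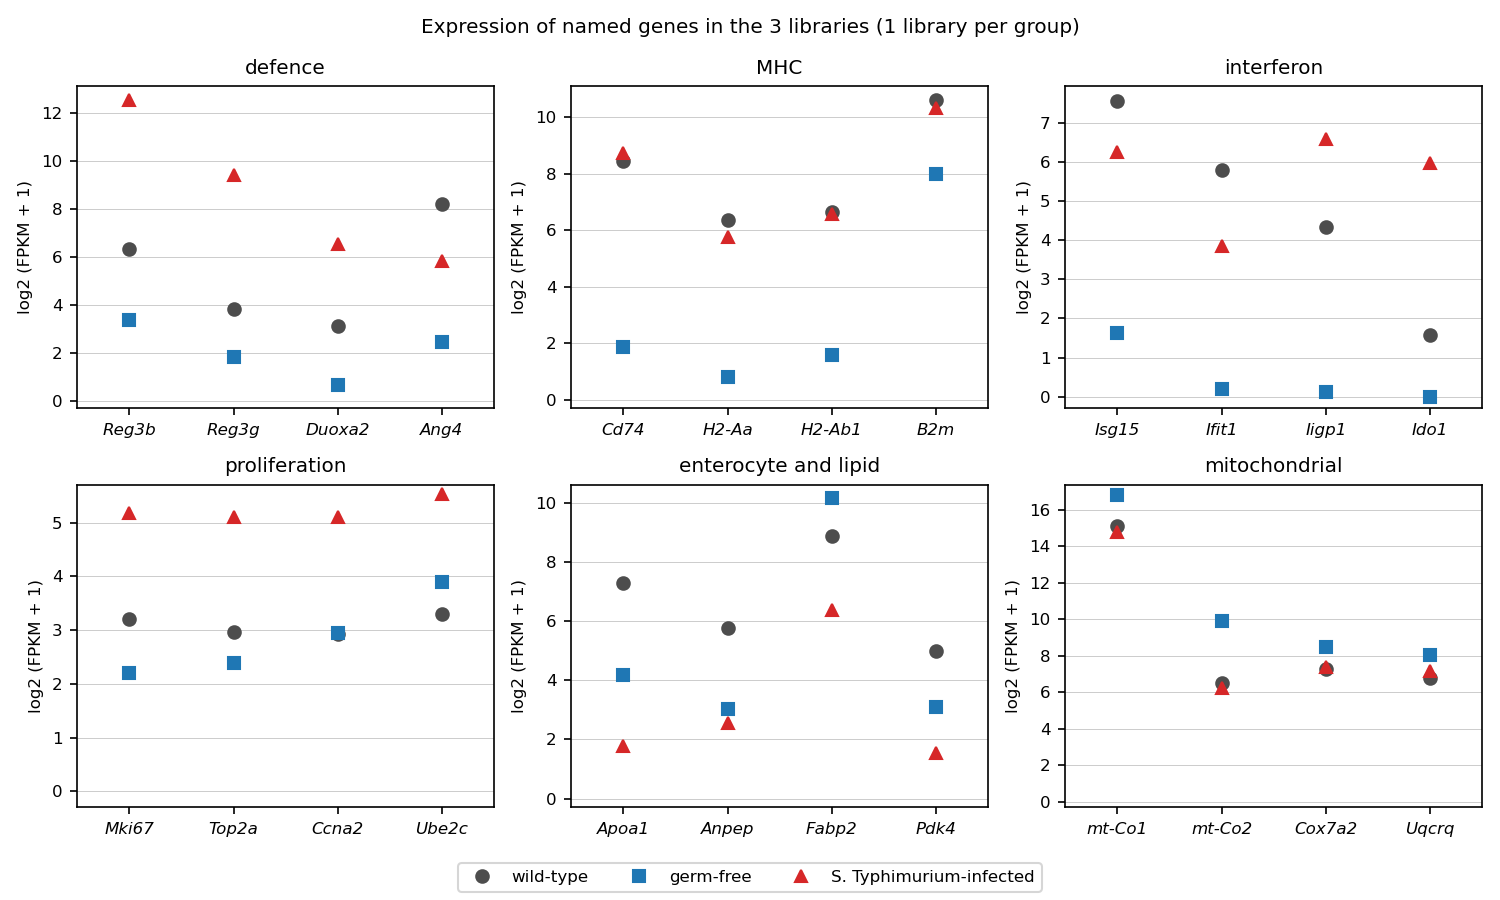
Expression as log2 of FPKM + 1 (vertical axis) of 24 named genes in 6 groups, with 1 point per library: wild-type circles, germ-free squares and infected triangles. Cd74 stands at 351, 2.68 and 424 FPKM and Reg3b at 81.2, 9.41 and 5963 FPKM in the wild-type, germ-free and infected library.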

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

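Ratios centred by abundance and gene length, random lists matched on length, the counts without mitochondrial, X and Y genes and the 20-read minimum were alternatives chosen only after the data were seen. Of 132 gene counts under alternatives 78 stayed within 1.5 times the reported count, 37 were smaller and 17 larger. Of 930 list medians 885 kept their side of the random lists, 27 moved inside, 15 moved outside and 3 that lay outside changed sign, and of 1442 values of named genes 1371 kept their side of the rule and no named gene past the rule changed sign. Part of these totals was fixed in advance. A gene under 1 FPKM in all libraries cannot pass the rule, so counts could not change without the filter. Filters leave the ratios of named genes as they were. Scalings by 1 factor per library hardly move list percentiles, because the random lists move too. The totals therefore overstate how far the results were put to a test. In the order higher and lower, then long non-coding higher and lower, a pseudocount of 0.1 gave 803, 1076, 69 and 101 genes for the germ-free library, 1079, 1037, 27 and 109 for the infected library, and 118 higher and 286 lower in both. A pseudocount of 5 gave 234, 180, 5 and 6, then 218, 200, 2 and 1, then 10 and 26. A 4-fold rule gave 43, 133, 3 and 4, then 77, 70, 1 and 1, then 3 and 12. A minimum of 5 FPKM gave 343 lower germ-free genes, 15 and 9 long non-coding, 7 and 9 long non-coding infected, and 65 lower in both. TPM gave 192, 2480, 18 and 137 for the germ-free library, 1102 higher, 24 and 70 long non-coding for the infected library, and 304 lower in both. Rescaling without the 100 most abundant genes gave 235 and 891 germ-free genes, 17 long non-coding higher, and 16 higher in both. Protein-coding genes alone gave 365 lower in the germ-free library and 61 in both, by having fewer genes. Centred ratios gave 305 germ-free genes higher and 19 higher in both, and at least 20 reads gave 17 long non-coding genes lower in the infected library and 72 genes lower in both. Medians of lists outside the random lists that changed sign were the germ-free enterocyte list (0.065) and the infected histone list (-0.049) at 5 FPKM or more, and the germ-free circadian list as TPM (-0.247), which stayed above its random lists at percentile 98.44. Changes of sign among lists inside the random lists, several of them under scalings, are not in this count. The germ-free circadian list also moved inside without the filter (0.050), at 5 FPKM (0.285), with quantile normalization (0.209) and by the mean (0.149). Germ-free neutrophil and macrophage markers moved inside with pseudocount 5 (-0.121), no filter (-0.124), 5 FPKM (-0.470), size factors over genes at 1 FPKM in all libraries (-0.466), without the 100 most abundant genes (-0.525), by the mean (-0.386) and matched on length (-0.437). Infected tuft cell markers did so with pseudocount 0.1 (-0.526), no filter (-0.091), TPM (-0.413), the mean (-0.307), centring (-0.391) and matching on length (-0.442). Infected immediate-early genes did so with pseudocount 0.1 (-0.273), TPM (-0.187), quantile normalization (-0.233), the mean (-0.045) and matching on wild-type values (-0.273). So did the germ-free NF-kB list (-0.173) and the infected proximal list (-0.005) without the filter, infected histones matched on wild-type values (0.567), and by the mean the germ-free stem cell (-0.299) and unfolded protein response (-0.142) lists. Lists that moved outside were germ-free nutrient transporters with pseudocount 5 (-0.140), quantile normalization (-0.221) and the mean (-0.328), and infected nutrient transporters without the filter (-0.171) and by the mean (-0.457). The others were germ-free ileum markers with quantile normalization (-0.335) and centring (-0.418), germ-free bile acid genes with centring (-0.418), germ-free lipid absorption (0.616) and histones (1.379) at 5 FPKM, germ-free histones by the mean (0.417), and infected well-characterised long non-coding RNAs without the filter (-0.074). Infected ribosomal genes did so at 5 FPKM (0.148), with quantile normalization (0.202) and matched on wild-type values (0.148). Apart from the smaller gene sets, the cause was not tested. As TPM the all-gene median was 0.103 in the infected library. With genes at 0 reads set at their bound, 4 of 13 list medians moved, those of germ-free interferon-gamma targets (-1.91), tuft cells (-1.18), neutrophil and macrophage markers (-0.32) and sex-linked transcripts (-7.41). No paired analysis was possible because each group was 1 library. Depth limited genes with few reads, since 3 reads in a 1 kb gene are 0.151, 0.199 and 0.129 FPKM in the wild-type, germ-free and infected libraries.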

Other observations

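All tests in this part were chosen after the data were seen, and for the 2 on the length and abundance trend of the germ-free library the bound was set before the value was seen. The glycolysis and hypoxia lists described first were also put together after their values had been seen, and they count as description only. Glycolytic enzymes had a median log2 ratio of 1.11 in the germ-free library with 8 of 14 higher and none lower. Ldha, lactate dehydrogenase, was 4.004-fold higher (3.93 to 4.08), Pgk1, phosphoglycerate kinase, 3.18-fold (3.08 to 3.28), and Pfkl, phosphofructokinase, 3.20-fold (3.10 to 3.31). Targets of hypoxia-inducible factors outside glycolysis had a median of 0.80 with 5 of 15 higher, led by Ak4 and Bnip3, with Ndrg1 3.14-fold higher (3.03 to 3.25). As TPM these germ-free medians were 0.524 for glycolysis and 0.217 for the hypoxia list. In the infected library the glycolysis median was 0.51 with 2 of 14 higher, among them Hk2, a hexokinase, 4.18-fold (4.01 to 4.36). The hypoxia list there lay inside the random lists at -0.11, and Ndrg1 was 2.58-fold lower (2.45 to 2.72).

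The posterior homeobox genes read were close in the 3 libraries. Hoxb13, a homeobox gene of the hindgut, was at 76.3, 77.2 and 67.1 FPKM in the wild-type, germ-free and infected libraries, and Hoxd13 was at 11.4, 12.7 and 13.5 FPKM. Interferon genes themselves were barely read: Ifnb1, Ifnl2 and Ifnl3 were listed at 0 in all 3 libraries, and Ifng had 9, 8 and 4 reads. These genes were picked after their values were seen.

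The first pattern was the lower MHC class I and II lists in the germ-free library. A variant H2 haplotype was argued against by 6 of 7 members outside chromosome 17, where the H2 complex lies, being at least 2-fold lower, and the length and abundance trend by a centred median of -2.17 for the joined lists. For class II, fewer B cells or macrophages could not be decided. The highest of their markers, Cd14, reached 7.21% of Cd74 in the wild-type library, under the 10% bound, and C1qa 1.16%. Such shares do not show how much Cd74 these cells would hold. This form was also chosen after a first one with neutrophil markers had given 10.7% (Ly6g), above its 10% bound, and that wider form stays undecided. Of 10 expressed neutrophil and macrophage markers 9 were below wild-type in the germ-free library, among them C1qb (1.39 to 0 FPKM). The 1 above it was C1qa (4.06 to 5.48 FPKM). Ly6g was at 37.5 and 32.6 FPKM in the wild-type and germ-free libraries, while Ptprc, the leukocyte common antigen, had a germ-free ratio of 0.354 (0.271 to 0.456). Sex cannot be told apart from colonisation, as Xist was at 9.68 FPKM in the germ-free library alone, so microbial induction of MHC genes is an untested hypothesis here.

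The second pattern was the higher oxidative phosphorylation list in the germ-free library. The length and abundance trend was argued against by a percentile of 100 among random lists matched on both, with a centred median of 0.51. Scaling as the whole cause was argued against by a median of 0.294 and a lower quartile of 0.191 as TPM, which lowers that library furthest of the scalings run, but none of the 30 members was then past the 2-fold rule, so the size of the difference depends on scaling. A first test used the percentile of ribosomal protein genes, which hardly moves with scaling because the random lists move too, and was set aside. The germ-free library also had more mitochondrial reads than the wild-type library (19.6% against 9.06%) and fewer genes with a read (18780 against 20948). Whether the 2 differed in RNA quality or cell preparation was not measured, and this stays open. Sex, which was not tested for this list, and single-library variation stay open too, so a metabolic difference that goes with the absence of microbes may be proposed only as a hypothesis.

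The third pattern was higher proliferation with lower enterocyte and lipid genes in the infected library. A more distal stretch of gut would raise colon markers, whose median was -0.96. That list also holds genes of differentiated cells, so its fall cannot decide this. More crypt base would raise stem cell markers, whose median was -0.12. More leukocytes would raise Ptprc, whose ratio in the infected library was 0.656 (0.548 to 0.785), although neutrophil and macrophage markers were higher at 0.99, so a change in the kind of leukocyte stays open. Among members of that list under 1 FPKM, Csf3r and Cxcr2 had 66 and 31 infected reads and 0 wild-type reads. Mmp9 went from 1 to 35 reads. C1qc, Adgre1 and Mmp8 were lower in FPKM, and Mpo was listed at 0 in both. Most of these few reads go with a change in the kind of leukocyte, which was not tested. These values do not show which epithelial cells were recovered in each preparation. A shift of the epithelium towards dividing, less differentiated cells on infection may be proposed only as a hypothesis, found and tested on the same single pair of libraries.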
